A study of Panicum virgatum with 18 samples.

How the data were processed

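RNA was taken from roots and shoots of switchgrass grown for 4 weeks at 3 levels of N supply, and the labels list 18 libraries. Per the labels' protocols, total RNA was extracted with a CTAB and lithium chloride method, treated with DNase, and made into libraries with a TruSeq RNA kit. The submitters' processing notes name HISAT2 2.0.5, StringTie 1.2.4 and Cuffdiff, without the role of each; the genome build is not given in the sources used here. Gene models carry names of assembled loci (MSTRG) or of the Pavir annotation, and the version suffix 4.1 appears in 22323 of them.

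The files are 6 tables of the authors' own comparisons, each of control shoots against 1 limited group. Per the file headers, the deposited columns are a mean normalized count, which is a signal that is never negative, a log2 fold change, its standard error, a test statistic or score, a p-value and an adjusted p-value. The column names are those DESeq2 writes, per the file headers, while the notes name Cuffdiff and no source used here names DESeq2, so which model the authors fitted is not known. The deposited statistic equalled the log2 fold change divided by its standard error. The mean normalized count was identical in all 6 tables, so the authors' values came from 1 joint scaling, over libraries that are not stated. The deposited standard errors did not exceed 1.42 even for the lowest counts, and log2 fold changes below a mean normalized count of 1 stayed within 3.40, so large changes of rare transcripts can be understated. Adjusted p-values were missing for 27058, 32816 and 34739 models at the severe, moderate and mild levels; these models were left out as not tested.

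The design fixed before the data were examined assumed FPKM values for each group. The files hold mean normalized counts over all libraries instead, so thresholds of 5 and 1 FPKM for naming genes were replaced, as that design provided, by the 50th and 25th percentile of the mean normalized count (22.8 and 2.41). The demand for a value above 0 in the lower group could not be applied. The sign of the deposited log2 fold changes was turned, so that positive means higher under limitation. Depth per library is unknown, so no interval or floor for counts could be given, and the precision of each value is the authors' standard error.

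A gene model counted as called at the authors' adjusted p under 0.05. The 27 gene lists were written before the data were examined: 24 hold 395 Arabidopsis genes, matched through the Arabidopsis best hit in the tables, and 3 (cytosolic ribosome, proteasome, heat shock proteins) were matched by words in the descriptions. An Arabidopsis hit was given for 43892 of 99409 models. Models without a reference gene (a dash in the table) numbered 25681 and held 70.5% of the summed mean normalized count, and no list can contain them. None of the tables' identifiers matched the reference gene table (assembly P.virgatum_v5), so no gene coordinates or lengths are given. Each list was tested by a two-sided Fisher's exact test for higher and for lower calls among all tested models, with Benjamini-Hochberg adjustment over 162 tests, and its median was placed among 10000 random lists matched on 10 classes of mean expression. Genes of 1 list are not independent, so these tests describe the tables. Counts "adjusted over the list alone" used the authors' p-values of the tested members.

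Overlap between levels was set beside the product of the list sizes over the genes tested in both, and beside 50 simulations of unchanged groups in which the control supplies 1 part in 2 of the smallest variance. Each simulated table contributed its top-ranked models by size of the statistic, as many as were called in the data, and no threshold was applied. Differences between levels were tested as the difference of log2 fold changes over the root of the summed squared standard errors, which overstates the error where a control is shared. Genes were named by a rule fixed before the data were examined: at each level the 5 largest called rises and 5 largest falls among annotated models at or above the 50th percentile, and from each list the 2 called members with the largest change under severe limitation at or above the 25th percentile. A further 6 genes were chosen after their values were seen.

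The tests were run on simulated data first. With errors of the severe table over 72351 models and 200 changed genes, 5.71% of genes changed by 0.5, 33.3% of those changed by 1 and 54.7% of those changed by 2 on the log2 scale were called, with 4 false calls. So few changed genes make the adjusted threshold stricter than in the severe comparison with its 15391 calls. The shares therefore do not give the sensitivity of that comparison. Simulated errors were drawn with the standard errors that the test used, so few false calls were built in. A planted list was recovered and none of the other 53 list tests was called. With errors of the severe and mild tables over 64670 models, the test of differences called none when none differed and 58.5% of 200 genes that differed by 2.

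Alternatives were a stricter adjusted p (0.01), a 2-fold minimum, Benjamini-Hochberg adjustment over all models with a p-value, centring on the median, 1 gene per Arabidopsis gene, and, chosen after seeing the data, a minimum at the median mean count, models with a reference gene only, a background of genes with an Arabidopsis hit, a ribosome list without organelle-type hits, and an allowance for the shared control. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The 3 tables of control shoots against shoots whose names carry the letter P were used only in the closing section.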

Results

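RNA was sequenced from switchgrass (Panicum virgatum, wild-type plants of the lowland cultivar Alamo) grown for 4 weeks with nitrogen (N) supplied at 2.0 mM (mild limitation), 0.6 mM (moderate) or 0.2 mM (severe). The labels list 18 libraries, 3 for each of the 6 combinations of organ and N level. The files hold 6 of the authors' own comparisons, each of control shoots on full nutrition against limited shoots, over 99409 gene models. Of these comparisons, 3 are the N levels reported here, and the 9 root libraries were not analysed here. The number of control libraries is not given in the sources used here. The values are summaries of the authors' model, so the read depth of each library and the spread between plants are not known beyond the standard error (SE) that the model gives. All fold changes are written as N-limited over control, the reverse of the order in the tables' names. That reading of the sign rests on the order of the names and on the phosphate starvation genes given in the closing section. Nothing in the labels says whether the 3 libraries of a group came from separate plants or pools, so the p-values measure only the spread between these libraries.

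The first question was how the shoot transcriptome differed between plants under severe N limitation and plants on full nutrition. The lists of nitrate transport and nitrate reduction held more higher calls than other genes, although most of their members were not called higher. The lists of the photosystems, the Calvin cycle, chlorophyll synthesis, jasmonate synthesis and the ribosome held more lower calls than other genes. In the authors' deposited table, 15391 of 72351 tested gene models had an adjusted p under 0.05, which is 21.3%, with 7138 higher and 8253 lower under severe limitation. The median log2 fold change was 0.94 among the higher and -1.06 among the lower gene models. Of the called models, 7753 changed by at least 2-fold. The median over gene models at or above the median mean count was -0.01.

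**Figure D1:**
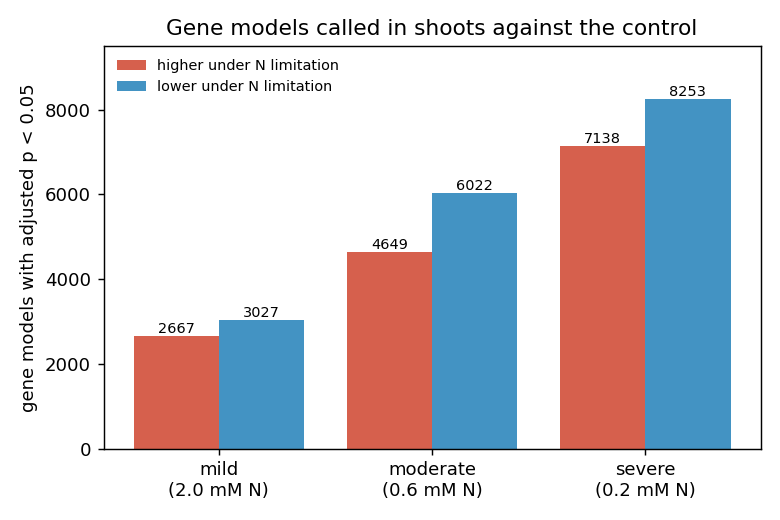
Bars give the number of gene models with an adjusted p under 0.05 in the authors' deposited tables (vertical axis) for shoots at each N level against the shared control (horizontal axis), split into models higher and lower under N limitation. Calls rose from 2667 higher and 3027 lower under mild limitation to 7138 higher and 8253 lower under severe limitation.

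Nitrate transport genes, fixed as a list from their Arabidopsis best hits, held 12 higher, 4 lower and 13 uncalled members among 29 tested under severe limitation (Fisher's exact test for higher calls, adjusted p = 7.86e-05). Adjusted over the list alone, 14 were higher and 4 lower. With 1 gene per Arabidopsis gene the adjusted p became 0.0760, the highest of 5 alternatives (lowest 2.39e-05). The authors' deposited table put 2 models with the high-affinity nitrate transporter NRT2.5 as best hit at log2 fold changes of 5.09 ± 0.46 (SE; MSTRG.34187, adjusted p = 2.16e-25) and 5.07 ± 0.48 (MSTRG.34176, adjusted p = 2.1e-23). These 2 models carry the same best hit and neighbouring numbers, so the division of reads between near copies is uncertain. A model whose best hit is CLCA, the vacuolar nitrate/proton exchanger of Arabidopsis, fell by 3.15 ± 0.28 in the authors' deposited table (MSTRG.57296; chosen after its values were seen).

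Genes of nitrate reduction and its supply of reductant held 8 higher and 4 lower members among 24 tested (adjusted p = 0.00891 for higher calls, Fisher's exact test; 10 higher and 6 lower adjusted over the list alone). In the authors' deposited table, the nitrate reductase hit NIA1 rose by 3.78 ± 0.44 (MSTRG.15321), which is 13.7-fold, and the root-type ferredoxin-NADP reductase hit RFNR1 rose by 2.72 ± 0.28 (MSTRG.68111). The nitrite reductase hit NIR1 rose by 1.98 ± 0.27 (MSTRG.35261) in the authors' deposited table. UPM1, which makes the siroheme precursor that nitrite reductase needs, was 3.24-fold higher in the authors' deposited table (MSTRG.39371). These 2 genes were chosen after their values were seen. Transporters of ammonium, urea and amino acids held 15 higher and 7 lower members among 56 tested (adjusted p = 0.00181 for higher calls, Fisher's exact test), the same counts as adjusted over the list alone. Similar counts of this list in another table that shares the control are given in the closing section. The ammonium transporter hits AMT2;1 rose by 3.30 ± 0.87 (MSTRG.35468) and 3.12 ± 0.72 (MSTRG.35504) in the authors' deposited table.

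Genes of ammonium assimilation and asparagine synthesis were called lower in 7 of 14 tested models and higher in 3, with the same counts adjusted over the list alone (Fisher's exact test for lower calls, adjusted p = 0.00268). That call was lost when only q under 0.01 (adjusted p = 0.295) or a change of at least 2-fold (adjusted p = 0.574) counted, and the lowest adjusted p of the 5 alternatives was 0.00579. The closing section gives the lower calls of this list in another table that shares the control. The members went in opposite directions: in the authors' deposited table the asparagine synthetase hit ASN3 was 4.38-fold higher with a log2 SE of 0.14 (MSTRG.25896), while the aspartate aminotransferase hit ASP1 fell by 2.01 ± 0.22 (MSTRG.5235). Regulators of the N response held 8 higher, 6 lower and 18 uncalled members among 32 tested, 11 and 9 adjusted over the list alone. Their median was -0.03, so the test for higher calls (Fisher's exact test, adjusted p = 0.04996) and the median differed in sign. This test missed the threshold under 4 of the 5 alternatives, whose adjusted p ran from 0.0166 to 0.297. The authors' deposited table gave a log2 fold change of 2.51 ± 0.20 for NLP5 (MSTRG.11555), of the NIN-like family of nitrate-response transcription factors, and -2.36 ± 0.26 for HHO1 (MSTRG.64841), of a family of nitrate-inducible repressors.

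Photosystem and light-harvesting genes were called lower in 32 of 50 tested models, with no member called higher and 18 uncalled (adjusted p = 5.73e-17, Fisher's exact test; 36 lower adjusted over the list alone). Their median log2 fold change of -1.12 lay below all 10000 random lists matched on mean expression. In the authors' deposited table, light-harvesting protein hits LHCB1.5 fell by 3.27 ± 0.35 (MSTRG.39184) and 3.14 ± 0.40 (MSTRG.75406). A model annotated as a chlorophyll a/b-binding family protein, with an early light-induced protein as rice hit and outside the list, stood at 4.34 ± 0.40 in the authors' deposited table (MSTRG.9148). It is 1 of 9 tested models of the chlorophyll a/b-binding domain family with such a rice hit, a group chosen after its values were seen, of which 8 were higher and 0 lower under severe limitation. Calvin cycle genes were lower in 16 of 22 tested models (adjusted p = 7.1e-10, Fisher's exact test; 17 adjusted over the list alone), with a median of -1.47. Lower calls of the photosystem and Calvin cycle lists in other tables that share the control are given in the closing section. The Rubisco small subunit hit RBCS1A fell by 2.78 ± 0.53 (MSTRG.21290) and the Rubisco activase hit RCA by 3.90 ± 0.78 (MSTRG.59110, mean normalized count 20.6) in the authors' deposited table. Chlorophyll biosynthesis genes were lower in 13 of 26 tested models (adjusted p = 1.36e-05, Fisher's exact test; 14 adjusted over the list alone), with PORA at -2.11 ± 0.48 (MSTRG.53897) and HEMF1 at -2.02 ± 0.21 (MSTRG.49703) in the authors' deposited table.

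The C4 carbon cycle list, for the pathway by which switchgrass concentrates CO2 around Rubisco, had 9 higher, 8 lower and 16 uncalled members among 33 tested, 12 and 11 adjusted over the list alone (adjusted p = 0.0203 for higher calls, Fisher's exact test). The call did not hold with 1 gene per Arabidopsis gene (adjusted p = 0.859) or among models at or above the median mean count (adjusted p = 0.185), and the lowest adjusted p of the 5 alternatives was 0.0179. The closing section gives similar counts of higher calls for this list in other comparisons that share the control. Its 2 members named by the rule were ALAAT2, called higher (MSTRG.11087, mean normalized count 9.1), and NADP-ME4, at -3.22 ± 0.70 (MSTRG.34607) in the authors' deposited table. For ALAAT2 the moderate table gives a log2 fold change of exactly 0 with a p of 1, as for a gene with no reads in either group, so its fold over the control is not given.

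Ribosomal protein genes formed the largest list, chosen by words in the descriptions to hold cytosolic members, with 200 lower, 5 higher and 274 uncalled among 479 tested under severe limitation (adjusted p = 7.28e-63 for lower calls, Fisher's exact test; 222 lower adjusted over the list alone). The changes were small: the median was -0.46 with quartiles of -0.74 and -0.19. The list still held 51 tested members whose hits name an organelle ribosome, among them the ribosomal protein L12-A hit with the largest called change, -3.48 ± 0.42 in the authors' deposited table (MSTRG.19811). Without these members 182 of 428 were lower (adjusted p = 1.25e-58, Fisher's exact test), with a median of -0.46. Heat shock protein genes were lower in 45 and higher in 6 of 141 tested models (adjusted p = 1.39e-09 for lower calls, Fisher's exact test; 49 lower and 6 higher adjusted over the list alone), with HSP20-like chaperones at -3.43 ± 0.47 (MSTRG.8318) and -3.25 ± 0.57 (MSTRG.8084) in the authors' deposited table. Other short-protein families also had medians below 0 at the severe level, as the closing section gives.

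Genes of jasmonate synthesis and its JAZ repressors were lower in 12 of 23 tested models and higher in none (adjusted p = 1.84e-05, Fisher's exact test; 13 lower adjusted over the list alone); with 1 gene per Arabidopsis gene the adjusted p was 0.123, the highest of 5 alternatives (lowest 8.86e-07). The same list in other tables that share the control is given in the closing section. JAZ1 stood at -2.61 ± 0.52 (MSTRG.70038) and LOX2, a lipoxygenase of jasmonate synthesis, at -2.75 ± 0.89 (MSTRG.47945) in the authors' deposited table. JAZ1 was below 0 at the other levels too, while LOX2 stood at 0.13 under moderate and 0.92 under mild limitation. Phenylpropanoid and lignin genes held 1 higher call among 88 tested, fewer than the share of all genes (adjusted p = 0.011, Fisher's exact test), and 17 lower calls, counts that were the same adjusted over the list alone. The shortage of higher calls was lost with 1 gene per Arabidopsis gene (adjusted p = 1), at 2-fold (adjusted p = 0.143) and at q under 0.01 (adjusted p = 0.0536), and the lowest adjusted p of the 5 alternatives was 0.00395.

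No other list passed the test in either direction under severe limitation. Chlorophyll breakdown and leaf senescence held 7 higher and 5 lower among 43 tested, with the NAC factor hit NAP at 1.91 ± 0.47 (MSTRG.56798) and the cysteine protease hit SAG12 at -3.09 ± 1.19 (MSTRG.5193, mean normalized count below the median of 22.8) in the authors' deposited table. The SAG12 hit had the opposite sign at the other levels, with 2.34 under moderate and 1.58 under mild limitation. Autophagy held 3 higher and 1 lower of 22, flavonoid and anthocyanin synthesis 7 and 3 of 52, the phosphate starvation response 6 and 2 of 47, and sulfate uptake and assimilation 3 and 0 of 7. Cytokinin genes held 0 higher and 4 lower of 30, starch and sucrose synthesis 0 and 4 of 22, starch breakdown 0 and 4 of 14, cell division 0 and 2 of 24, pathogenesis-related genes 2 and 5 of 24, and the proteasome 4 and 13 of 63. Of these lists only the proteasome count changed adjusted over the list alone, to 4 higher and 18 lower. Beta-amylase hits BAM5 fell by 3.66 ± 0.45 (MSTRG.11964) and 2.41 ± 0.29 (MSTRG.16885), and the cytokinin response regulator hit ARR6 by 1.97 ± 0.31 (MSTRG.53848), in the authors' deposited table.

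Markers of other organs and tissues were examined beside these groups. Root markers had 2 higher and no lower calls among 20 tested, the Casparian strip protein hit CASP5 (MSTRG.11604) and the auxin efflux carrier hit PIN2 at 2.18 ± 0.48 (MSTRG.34904) in the authors' deposited table. CASP5 stood at exactly 0 with a p of 1 in both other N tables, so its fold over the control is not given. Floral markers had no call among 19 tested, and genes of the secondary wall of stems had 2 higher and 1 lower among 14, with 2 models of the xylan synthesis hit IRX10 at 0.85 ± 0.26 (MSTRG.67507) and 0.84 ± 0.24 (MSTRG.29526) in the authors' deposited table. None of these 3 lists passed the test.

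The largest single falls under severe limitation were of a chitinase family protein at -9.48 ± 1.09 (MSTRG.29107), polyamine oxidase 1 at -7.23 ± 0.78 (MSTRG.29358), ureide permease 4 at -6.96 ± 0.83 (MSTRG.47343), a ribonuclease T2 family protein at -6.79 ± 0.46 (MSTRG.11472) and a sterol-4alpha-methyl oxidase at -6.77 ± 0.50 (MSTRG.33313), among expressed and annotated models of the authors' deposited table. Ureide permeases carry N-rich ureides and nucleobases, and ribonucleases of the T2 family degrade RNA. The largest rises in the authors' deposited table were of an NB-ARC disease resistance protein at 5.79 ± 1.34 (MSTRG.58679), RAD-like 6 at 5.64 ± 0.69 (MSTRG.33749), a DNA-binding protein with a transposon protein as rice hit at 5.63 ± 1.13 (MSTRG.49444), receptor like protein 6 at 5.54 ± 1.07 (MSTRG.29614) and WRKY55 (MSTRG.40546). RAD-like 6, a small MYB-related protein, was called higher at all 3 N levels. The NB-ARC model MSTRG.58679 stood at 0.88 under moderate and 4.23 under mild limitation. WRKY55 stood at exactly 0 with a p of 1 in both other N tables, so its fold over the control is not given. These 5 models had mean normalized counts between 27.7 and 62.5, and means of each group are not given in the table.

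The second comparison set shoots under moderate N limitation against the same control. The nitrate reduction list again held more higher calls than other genes, and the photosystem, chlorophyll, jasmonate and ribosomal lists more lower calls. Calvin cycle genes were called lower in 1 of 22 tested models, with a median of -0.49 and quartiles of -0.97 and -0.38. Differences between levels were not tested for this list. The authors' deposited table called 10671 of 66593 tested gene models (16.0%), 4649 higher and 6022 lower, with 5159 changed at least 2-fold. Nitrate reduction and reductant supply held 9 higher and 3 lower of 23 (adjusted p = 0.000105, Fisher's exact test; 10 and 4 adjusted over the list alone), with NIA1 at 3.00 ± 0.44 and RFNR1 at 2.91 ± 0.28 in the authors' deposited table. Nitrate transport held 6 higher and 3 lower of 27 (adjusted p = 0.0455 for higher calls, Fisher's exact test; 6 and 4 adjusted over the list alone), a call lost against the background of genes with an Arabidopsis hit (adjusted p = 0.0658) and with 1 gene per Arabidopsis gene (adjusted p = 0.139). The lowest adjusted p of its 5 alternatives was 0.0207.

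Transporters of ammonium, urea and amino acids held 12 higher and 9 lower of 54 under moderate limitation (adjusted p = 0.00193 for higher calls, Fisher's exact test; 14 and 13 adjusted over the list alone). The call was lost at q under 0.01 (adjusted p = 0.235) and with 1 gene per Arabidopsis gene (adjusted p = 0.499), and the lowest adjusted p of the 5 alternatives was 0.000892. N regulators were called in both directions, 8 higher and 8 lower of 32, the same counts as adjusted over the list alone (adjusted p = 0.00775 and 0.0327, Fisher's exact test), with a median of -0.02. The lower calls missed the threshold under 3 of the 5 alternatives, whose adjusted p ran from 0.0251 to 0.326. Ammonium assimilation genes were lower in 6 of 14 models (adjusted p = 0.00538, Fisher's exact test; 7 adjusted over the list alone), a call lost at 2-fold (adjusted p = 0.99, the highest of 5 alternatives; lowest 0.0103). Sulfate uptake genes were higher in 3 of 6 (adjusted p = 0.0303, Fisher's exact test; 4 adjusted over the list alone), with the sulfate transporter hits SULTR2;1 at 0.93 ± 0.33 (MSTRG.63579) and 1.15 ± 0.20 (MSTRG.63578) in the authors' deposited table; 4 of 5 alternatives ended that call, with adjusted p from 0.0379 to 0.562.

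Photosystem genes were lower in 21 of 50 models under moderate limitation (adjusted p = 1.05e-08, Fisher's exact test; 29 adjusted over the list alone) and chlorophyll biosynthesis genes in 13 of 26 (adjusted p = 1.03e-06, Fisher's exact test; 14 adjusted over the list alone). Of the 29 models of the chlorophyll a/b-binding domain family, 9 were higher (adjusted p = 0.00567, Fisher's exact test over 833 domain families) and 6 lower, and all 9 have an early light-induced protein as rice hit and lie outside the photosystem list. The LHCB1.5 hits stood at -2.43 ± 0.35 (MSTRG.39184) and -1.80 ± 0.40 (MSTRG.75406) in the authors' deposited table. Jasmonate genes were lower in 13 of 22 models (adjusted p = 7.55e-08, Fisher's exact test; 14 adjusted over the list alone). Ribosomal protein genes were lower in 190 of 467 (adjusted p = 1.03e-73, Fisher's exact test; 218 adjusted over the list alone), with a median of -0.47. Heat shock protein genes passed the test in neither direction, with 14 higher and 7 lower of 136 tested.

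Among expressed, annotated models of the authors' deposited table at the moderate level, the largest falls were of the same chitinase at -8.41 ± 1.05, 2 lactoylglutathione lyase (glyoxalase I) family proteins at -6.10 ± 0.59 (MSTRG.36961) and -5.67 ± 0.66 (MSTRG.37001), polyamine oxidase 1 at -5.94 ± 0.73 and an acid phosphatase of the HAD superfamily at -5.24 ± 0.75 (Pavir.5KG134800.v4.1). The largest rises there were of a BED zinc finger protein with the dimerisation domain of hAT transposons at 6.10 ± 1.31 (MSTRG.22773), receptor like protein 6 at 5.54 ± 1.07, RAD-like 6 at 5.40 ± 0.69, the chlorophyll a/b-binding family protein MSTRG.9148 at 4.78 ± 0.40 and farnesyl diphosphate synthase 1 at 4.70 ± 1.27 (MSTRG.50097) in the authors' deposited table. MSTRG.22773 stood at 0.22 under severe and 4.32 under mild limitation, so its rise did not follow the N supply.

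The third comparison set shoots under mild limitation, at 2.0 mM N, against the control. The lists of nitrate transport, nitrate reduction and N regulators held more higher calls than other genes, though fewer than the uncalled members in each. The ribosomal, heat shock and chlorophyll biosynthesis lists held more lower calls, and no photosystem gene was called. For the photosystem list the difference between levels was not tested. In the authors' deposited table, 5694 of 64670 tested gene models were called (8.80%), 2667 higher and 3027 lower, and 2294 changed at least 2-fold. Nitrate transport held 9 higher and 3 lower of 27 (adjusted p = 8.77e-06, Fisher's exact test; 10 and 3 adjusted over the list alone), led by the NRT2.5 hits at 6.55 ± 0.46 and 6.37 ± 0.48 in the authors' deposited table. Nitrate reduction and reductant supply held 7 higher and 4 lower of 23 (adjusted p = 0.000212, Fisher's exact test; 7 and 5 adjusted over the list alone), and here the median of -0.08 differed in sign from the test. N regulators held 12 higher and 1 lower of 32 (adjusted p = 3.63e-08, Fisher's exact test; 12 and 2 adjusted over the list alone), with NLP5 4.34-fold higher (log2 SE 0.20) in the authors' deposited table. Transporters of ammonium, urea and amino acids held 10 higher and 4 lower of 52 (adjusted p = 0.000333 for higher calls, Fisher's exact test; 16 and 4 adjusted over the list alone), a call lost with 1 gene per Arabidopsis gene, where 0 of 10 were called higher (adjusted p = 1; lowest of 5 alternatives 1.96e-06).

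Photosystem genes had a median of -0.40 under mild limitation, below all 10000 matched random lists, although none of 50 was called, also adjusted over the list alone. Chlorophyll biosynthesis genes were lower in 8 of 25 models (adjusted p = 0.000103, Fisher's exact test; 11 adjusted over the list alone), a call lost at 2-fold, where 0 counted (adjusted p = 1, the highest of 5 alternatives; the lowest was 0.000163). Ribosomal protein genes were lower in 205 of 463 and higher in none (adjusted p = 2.1e-142, Fisher's exact test; 269 lower adjusted over the list alone), with a median of -0.57. Heat shock protein genes were lower in 25 and higher in 4 of 131 (adjusted p = 3.22e-08 for lower calls, Fisher's exact test; 36 and 7 adjusted over the list alone). Their median was -0.29, and medians of similar size in tables that share the control are given in the closing section. The largest falls in the authors' deposited table at this level were the chitinase at -6.86 ± 1.01, 2 thioredoxin superfamily proteins at -5.17 ± 0.72 (MSTRG.32310) and -4.36 ± 0.41 (MSTRG.21623), a subunit of mitochondrial import at -4.46 ± 0.79 (MSTRG.62772) and a cytochrome P450 at -4.27 ± 0.74 (MSTRG.41375). After the 2 NRT2.5 hits, the largest rises in the authors' deposited table were farnesyl diphosphate synthase 1 at 5.32 ± 1.27, RAD-like 6 at 4.94 ± 0.69 and a trypsin family protein at 4.74 ± 1.07 (MSTRG.16514).

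**Figure D2:**
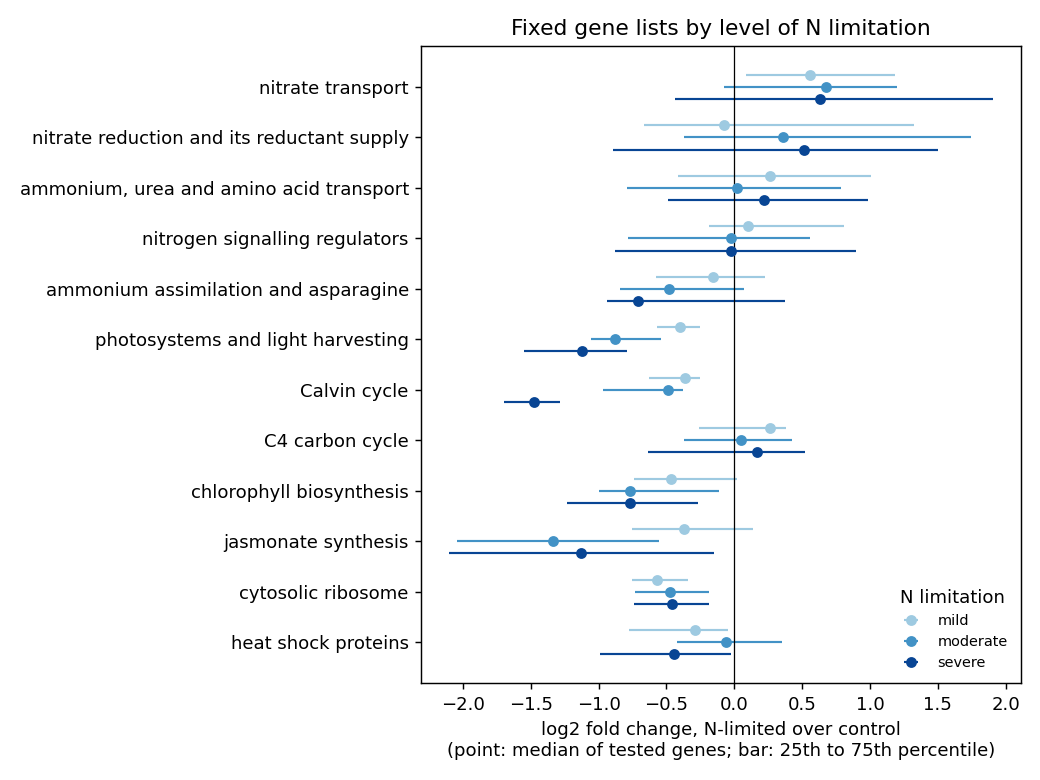
Points give the median log2 fold change, N-limited over control, of the tested members of 12 gene lists at each N level, and bars run from the 25th to the 75th percentile of the members (horizontal axis, log2 scale). Photosystem medians lie at -0.40, -0.88 and -1.12 from mild to severe, while ribosomal medians lie at -0.57, -0.47 and -0.46.

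The 3 N comparisons were then set against each other. Gene models called in the same direction at all 3 N levels numbered 3200, of which 1419 were higher and 1781 lower; 66 models were called in opposite directions at 2 levels. Independent lists of these sizes would share 55.9 models. Among the models at or above the median mean count, 3074 were shared, against 1199 in simulations of unchanged groups that share 1 control. Among the same models, severe and moderate limitation shared 7125 calls in the same direction, against 3974 in these simulations. Severe and mild limitation shared 3928, against 2445, and moderate and mild 3452, against 1965. The simulated figures are overlaps of the top-ranked models, as many as were called in each table, and not overlaps of calls. Across genes, which are not independent replicates, the log2 fold changes at the severe and moderate levels had a covariance of 0.46 (correlation 0.73), and unchanged groups gave 0.079 (0.49). For severe and mild limitation the covariance was 0.34 (correlation 0.64) against a simulated 0.079 (0.48), and for moderate and mild it was 0.31 (0.67) against 0.079 (0.48). The control libraries could not be split, so the share of each excess that the control adds is not known. Covariances of the N levels with another table that shares the control are given in the closing section.

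The last comparison concerned the order of the levels. Of the 15391 models called under severe limitation, 6690 (43.5%) had log2 fold changes ordered mild, moderate, severe away from the control, and simulated equal effects at all 3 levels gave 21.4%. The simulated effect of each model was its mean observed change, taken after the selection at the severe level. Selection therefore acted less in the simulations than in the data, so 21.4% may be too low a baseline. The median change of these called models, taken in the direction of the severe change, was 0.50 at the mild, 0.67 at the moderate and 1.01 at the severe level; selection at the severe level raises the last value. A test of the difference between the severe and mild log2 fold changes, with no allowance for the shared control, found 651 of 64670 models to differ, 187 with a higher and 464 with a lower value under severe limitation. Between severe and moderate limitation 219 models differed and between moderate and mild 438. With the control taken as 1 part in 2 of the smaller variance, an allowance chosen after seeing the data, these counts were 4750, 2225 and 2647. The LHCB1.5 hit MSTRG.39184 differed by -2.41 ± 0.50 between severe and mild (adjusted p = 0.000737, normal approximation on the authors' SE), and ASN3 by 0.96 ± 0.20 (MSTRG.25896, adjusted p = 0.00064). Both genes had been named for their change under severe limitation, which favours such a difference. The NRT2.5 hits did not follow that order: their values were highest at the mild level, and the differences of -1.46 ± 0.65 and -1.30 ± 0.67 between severe and mild had adjusted p of 0.422 and 0.584, or 0.0267 and 0.0720 with the allowance for the shared control.

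**Figure D3:**
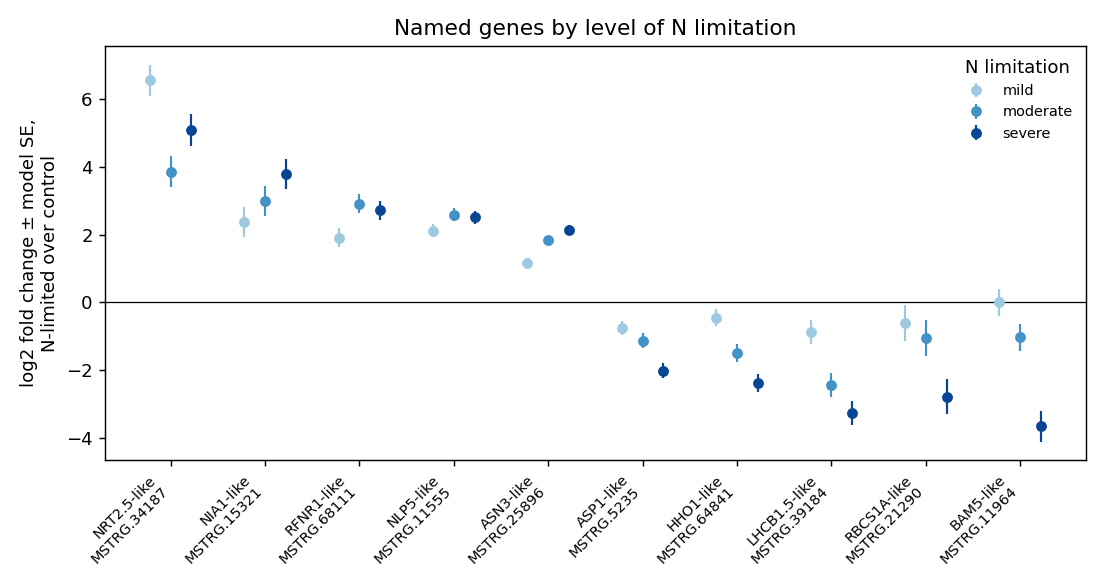
Points give the log2 fold change, N-limited over control (vertical axis), of 10 gene models, labelled by Arabidopsis best hit, at the mild, moderate and severe N levels, and bars give the SE of the authors' model. The NRT2.5 hit stands at 6.55, 3.86 and 5.09 from mild to severe, and the LHCB1.5 hit at -0.86, -2.43 and -3.27.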

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

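The tests of the 3 patterns weighed here and in the last part were all chosen after related results had been seen; the test between the severe and mild levels was also added after seeing the data. It flagged 16 named genes whose log2 fold change differed between these levels, given here as severe minus mild. In each of them the change was larger in size under severe limitation. Most had been named for a large change at that level, and this selection favours that direction. Lower values under severe limitation were found for polyamine oxidase 1 (MSTRG.29358, -5.60), the ribonuclease T2 family protein (MSTRG.11472, -4.86), the sterol-4alpha-methyl oxidase (MSTRG.33313, -4.12), ureide permease 4 (MSTRG.47343, -3.34) and the lactoylglutathione lyase family protein MSTRG.36961 (-3.06). The BAM5 hits differed by -3.66 (MSTRG.11964) and -2.63 (MSTRG.16885), the LHCB1.5 hits by -2.41 (MSTRG.39184) and -2.56 (MSTRG.75406), and the ribosomal L12-A hit by -2.23 (MSTRG.19811). HHO1 differed by -1.92 (MSTRG.64841), ASP1 by -1.26 (MSTRG.5235), HEMF1 by -1.19 (MSTRG.49703) and SS2, a starch synthase, by -0.97 (MSTRG.60573). Higher values under severe limitation were found for the chlorophyll a/b-binding family protein (MSTRG.9148, 2.42) and ASN3 (MSTRG.25896, 0.96). These 16 genes rest on the test with no allowance for the shared control. With the allowance further named genes passed, among them SAG12 (-4.67, adjusted p = 0.00356, normal approximation on the authors' SE). By the same test RBCS1A (-2.17, adjusted p = 0.00172) and NIA1 (1.39, adjusted p = 0.0286) passed too.

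Tables outside the 3 N comparisons also held changes. The 3 tables of control shoots against shoots whose names carry P with 20, 60 and 200 called 18040, 9036 and 3659 gene models in that order. The labels used here do not describe those plants. Across genes, the table with P and 20 had covariances of 0.41, 0.32 and 0.20 with the severe, moderate and mild N levels. The correlations were 0.50, 0.46 and 0.34. Simulated unchanged groups gave covariances of 0.08 and correlations of 0.49, 0.48 and 0.48. Heat shock protein genes had medians of -0.32, -0.31 and -0.28 in the 3 tables with P, which share the control, and of -0.44, -0.06 and -0.29 at the severe, moderate and mild N levels. With P and 20, Calvin cycle genes were lower in 14 of 22 models (median -1.55). Photosystem genes were lower there in 16 of 50 (-0.69) and ammonium assimilation genes in 7 of 14 (-0.69). Ammonium, urea and amino acid transport held 13 higher and 7 lower of 57. Nitrate transport held 2 and 4 of 29, and nitrate reduction 0 and 7 of 24. With P and 200, 2 of 22 Calvin cycle and 0 of 50 photosystem genes were lower. The C4 carbon cycle list held 9 higher and 14 lower of 33 with P and 20, 9 and 2 of 32 with P and 60, and 7 and 0 of 30 with P and 200. Its counts were 9 and 8 of 33, 6 and 4 of 32, and 2 and 2 of 31 at the severe, moderate and mild N levels. Differences from the N tables were not tested.

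The ribosomal list held 200 lower calls among 479, 190 among 467 and 205 among 463 tested from severe to mild, with medians of -0.46, -0.47 and -0.57. High values in the control libraries alone are argued against as the whole cause by the table with P and 200, which shares the control. There the ribosomal median was -0.087 (95% bootstrap interval over genes -0.11 to -0.07). That argument fails if the treatment with P and 200 raised the ribosomal genes by as much. The medians with P and 20 and with P and 60 were -0.10 and -0.22, so the control stays open as a part. Bootstrap intervals here and in the last part could resample genes only, not libraries. They leave out the spread between libraries, so arguments that rest on them hold for these libraries only. Low readings of short genes are argued against as the whole cause: from severe to mild the ribosomal genes changed by a median of -0.076 (interval -0.10 to -0.05), and 15 other families of short proteins, some noticed before they were chosen, by 0.12 (interval 0.08 to 0.17). Such readings stay open as a part, since these families had medians of -0.28 (interval -0.33 to -0.22), -0.15 and -0.16 from severe to mild, long-protein families had 0.27, 0.15 and 0.15, and gene lengths were not used here. Under severe limitation all 15 short-protein families had medians below 0, and 12 of 13 long-protein families had medians above 0. Whether protein length has a part in the higher or lower calls of the other lists was not tested. A criterion on the severe level alone could not decide. For such readings it asked for a short-protein median at or below -0.30 and a long-protein median above 0.15. Against them it asked for a short-protein median above -0.15. The long-protein part was met with 0.27, while the short-protein median of -0.28 lay between the bounds, with an interval that included -0.30. Scaling between libraries, which moves all genes alike, is argued against as the whole cause, since the ribosomal median lay below all 10000 lists matched on mean expression at each N level (95% of them between -0.13 and 0.00 under severe limitation).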

How the results depend on the processing

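The alternatives with the median mean count, the reference gene, the Arabidopsis background, the ribosome list without organelle-type hits and the control allowance were chosen after seeing the data. At q under 0.01, calls numbered 9675, 6317 and 2716 at the severe, moderate and mild levels, and calls shared by all 3 numbered 1509. With at least a 2-fold change they numbered 7753, 5159 and 2294, with 1051 shared. Models with a reference gene held 9816, 6872 and 3623 calls. These counts are smaller by construction. The share of severe calls ordered over the levels was 45.7% at 2-fold; the cause was not tested. Allowing for the shared control shrinks the error and raised the models that differ between severe and mild to 4750. Over all models with a p-value, or above the median mean count, no count of calls moved by over 1.5 times. Centring moved values by 0.01 and cannot change calls that rest on the authors' adjusted p. Of 30 list results, 21 passed with 1 gene per Arabidopsis gene, 26 at q under 0.01, 26 with at least a 2-fold change, 27 against the Arabidopsis background and 26 above the median mean count. The ribosome result passed at all 3 levels without organelle-type hits. Ammonium, urea and amino acid transport at the mild level lost its call with 1 gene per Arabidopsis gene (adjusted p = 1, Fisher's exact test), and chlorophyll biosynthesis at the mild level at 2-fold (adjusted p = 1, Fisher's exact test), each with 0 genes counted. Of 160 calls of named genes, 7 missed the threshold when adjusted over all models with a p-value, 23 at q under 0.01 and 25 at 2-fold. Leaving out replicates, the FPKM filter and log2(FPKM + 1) were not run, since the tables hold no values per library. No paired analysis was possible because the tables carry no replicate numbers, and for the same reason no other splits of the samples were drawn. Unknown depth limits all of these results.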

Other observations

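The gene families and all tests in this part were chosen after their values or related results were seen. Genes with a TIFY domain, most of which encode JAZ repressors of jasmonate signalling, were lower in 24 of 39 tested models under severe limitation and 27 of 39 under moderate limitation, and higher in none (Fisher's exact test, adjusted p = 5.59e-12 and 1.43e-17). Under mild limitation 2 of 39 were lower. The p-values in this part were adjusted over the tests of the TIFY and glutaredoxin families alone, not over all domain families. Their background had 12.6% of models lower under severe limitation, against 11.4% of all tested models. The fixed jasmonate list also holds JAZ genes such as JAZ1, so the TIFY result is not separate from it. In the authors' deposited table, the JAZ10 hit MSTRG.51563 stood at -4.33 ± 0.55 under moderate and -2.49 ± 0.53 under severe limitation, and the JAZ11 hit MSTRG.67278 at -3.03 ± 0.75 under severe limitation. The fixed list of jasmonate synthesis and JAZ genes had medians of -1.28, -0.82 and -0.57 in the tables whose names carry P with 20, 60 and 200, with 13 of 23, 11 of 22 and 3 of 22 lower, and of -1.13, -1.33 and -0.37 at the severe, moderate and mild N levels. The tables with P had 34 of 40, 27 of 39 and 9 of 38 of the TIFY models lower. All tables share the control, so these counts are not independent of each other.

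Glutaredoxins that the rice annotation places in subgroup III, a plant class of small redox proteins, were lower in 13 of 29, 11 of 24 and 12 of 24 tested models at the severe, moderate and mild levels (Fisher's exact test, adjusted p = 5.73e-05, 2.96e-05 and 4.38e-09). Their medians were -1.11, -0.78 and -1.09, and the short-protein families weighed above had -0.28, -0.15 and -0.16. Whether short length has a part in the glutaredoxin result was not tested. One of them, MSTRG.21621, stood in the authors' deposited table at -5.99 ± 0.48, -3.89 ± 0.42 and -4.05 ± 0.43. In the tables with P and 20, 60 and 200, 9 of 29 (adjusted p = 0.0345, Fisher's exact test), 2 of 24 and 0 of 22 were lower, and the difference from the N tables was not tested.

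Genes changed the same way in all 6 tables numbered 595. Among models at or above the median mean count they numbered 575, against 228 in simulations of unchanged groups. The simulations took as many top-ranked models as were called in each table. If the control libraries alone stood apart for the 595 genes, their change would be as large under mild as under severe limitation. The median of severe minus mild was 0.30 on the log2 scale (95% bootstrap interval 0.27 to 0.34), and 83.0% were larger under severe limitation, which argues against the control as the whole cause. A control that adds a constant part to every table may still account for some of the change, since the median size was 0.92 under mild limitation and 0.94 in the table with P and 200.

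The direction of every comparison rests on reading the deposited log2 fold change as control over limited. The sign was read from the order of the names and from the phosphate starvation genes given next, so these genes are not a separate check. If the sign were the other way round, genes of the phosphate starvation list would be expected to have positive deposited values in the table with P and 20, should P stand for phosphorus. Only 3 of its 33 called members did (9.09%). That argues against the opposite sign, under the assumption about the letter, which the labels used here do not state.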
